A study of Homo sapiens with 15 samples.

How the data were processed

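RNA sequencing was carried out on UKE-1 cells, an established human myeloid cell line derived from a patient with a myeloproliferative disease and widely used because it carries an activating mutation of the kinase JAK2. The 15 libraries fell into 5 groups of 3: untreated cells, cells stimulated with TNF-α, and TNF-α stimulated cells given MCL, ruxolitinib or both. MCL is taken here as micheliolide, the sesquiterpene lactone in the title of the series, and ruxolitinib is an inhibitor of the kinases JAK1 and JAK2. Per the labels, RNA was taken 3 h after treatment. The doses, the length of the TNF-α stimulation before the drugs, and whether the 3 libraries of a group came from separate cultures are not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical.

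The deposited table held raw counts, whole numbers of reads per gene as the authors made them, for 58735 genes and 15 libraries, with no normalization. The submitters' processing notes list HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the genome builds hg38 and mm10, with no role or order. The gene coordinates of the table were compared with the GENCODE 29 annotation of hg38, and 58735 of 58735 genes had the same start, end and symbol. Strand use, the treatment of reads that match several places, and the read filters are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be separated, and 83 of the 280 genes examined by name overlap another tested gene. The columns of the table headed as control were taken as the untreated group, the one group of the labels without TNF-α or a drug.

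Library totals ranged from 15476399 to 18035604 counts, with a count in 22819 to 24407 genes. Genes with low counts were removed with edgeR's filterByExpr at a minimum count of 10, which left 16146 genes and took out 42589. The tested genes held at least 99.85% of the counts of each library. Within groups, pairs of libraries differed by more than sampling noise in a chi-square test of their counts, so no library was treated as a copy of another. The biological coefficient of variation was 0.04, a low spread at which small changes pass the test.

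Differences were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, 1 model with a coefficient per group over all 15 libraries (10 residual degrees of freedom), the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment over all tested genes. A gene passed at an adjusted p under 0.05. A standard error is the log2 fold change divided by the square root of F. There were 7 comparisons of 2 groups, and an 8th contrast gave the non-additive effect of the combination, which is the log2 change with both drugs minus the sum of the log2 changes with each drug alone, all against TNF-α. Its value equals the log2 effect of MCL in the presence of ruxolitinib minus that in its absence. Levels are CPM, counts scaled to a common library total with TMM factors, as mean ± SD of 3 libraries.

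The tests of the comparisons, the gene lists, the rule for named genes and all alternatives were fixed before the data were examined. Some tests of explanations were chosen later, which is said where they appear. Of the 23 lists, each compared with all other tested genes by camera of limma 3.58.1 with a preset correlation of 0.01 between genes, p-values were adjusted over the lists within a comparison. Camera was also run with an estimated correlation, which raises p for lists whose members vary together. With the preset value 99 of 184 list tests passed, and 70 passed with an estimated correlation. Unless said otherwise, a printed camera adjusted p is the one with the preset value. For lists whose members vary together it can be far smaller than the one with an estimated correlation. Counts adjusted over the list alone correct for the members of that list only. The lists were textbook knowledge and shared some members.

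Genes were named by rule: the 8 with the highest and the 8 with the lowest fold change in each comparison of 2 groups, among protein-coding genes that passed, with a mean of at least 5 CPM in the higher group and libraries of the groups not overlapping. Up to 4 passing members of each list with the smallest p were added, as were 26 panel genes of the JAK-STAT, NF-kB and stress pathways in all comparisons. For the non-additive effect the 5 highest and 5 lowest genes were taken without the overlap condition. Other genes were chosen after their values were seen, which is said where they appear. Some genes that the rule names are not reported here.

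The scripts were tested on simulated counts with known changes. For TNF-α against untreated, 92% of genes changed 4-fold, 84% of those changed 2-fold, 60% of those changed 1.5-fold and 44% of those changed 1.25-fold were recovered. There were 8 false calls among the genes left unchanged, out of 16146 genes in all. For the non-additive effect the shares were 78%, 74%, 46% and 20%, again with 8 false calls. Only 50 genes were changed at each fold, far fewer than passed in the data. The adjusted threshold of the simulation was therefore stricter, and the shares do not give the sensitivity of the comparisons reported. The alternatives were DESeq2 size factors in edgeR, library totals alone, the DESeq2 1.42.0 Wald test, no filter, a filter at a mean of 50 counts, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Effects of comparisons that share the TNF-α libraries were simulated 10 times with unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.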

Results

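The libraries measured the RNA of UKE-1 cells in 5 groups of 3: untreated cells, TNF-α stimulated cells, and TNF-α stimulated cells given MCL, ruxolitinib or both drugs. TNF-α served to mimic an inflammatory environment, and the series concerns the action of micheliolide on STAT3 and STAT5 in myeloproliferative neoplasms. Total counts per library ranged from 15476399 in MCL replicate 2 to 18035604 in untreated replicate 2. Mitochondrial transcripts made up 5.22% ± 0.115 of the counts in untreated cells, 5.12% ± 0.151 with TNF-α, 4.55% ± 0.217 with MCL, 5.49% ± 0.0476 with ruxolitinib and 4.3% ± 0.143 with both drugs (SD, n = 3 each). The first principal component of log2 CPM held 38.6% of the variance and the second 20.5%. The combination lay farthest from the other groups along the first component, and the untreated libraries lay apart along the second.

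**Figure D1:**
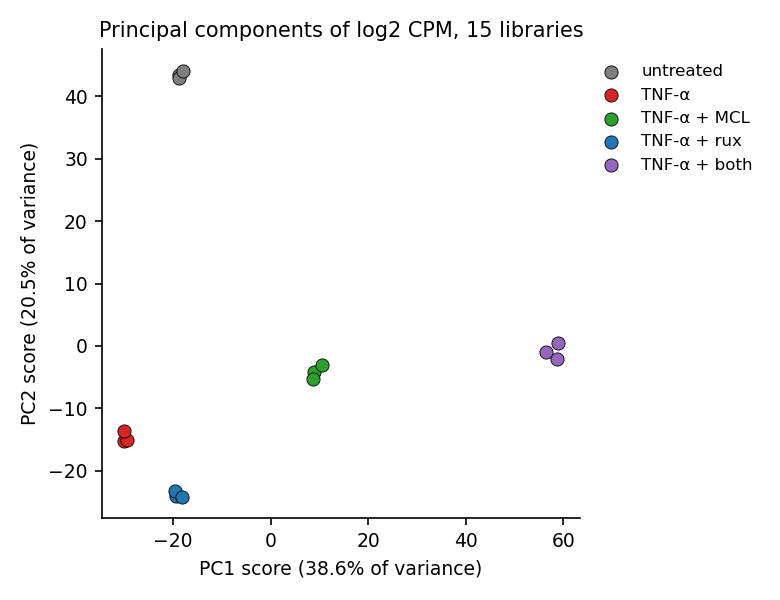
Scores of the 15 libraries on the first (x axis, 38.6% of the variance) and second (y axis, 20.5%) principal components of log2 CPM, 1 point per library and coloured by group. The 3 libraries of each group lie together, and those of the combination lie between 56.5 and 58.9 on the first component.

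TNF-α turned on NF-kB target genes and interferon-stimulated genes in UKE-1 cells. Their median log2 changes were 2.25 and 0.80, a difference between lists that was not tested. Transcripts of the adhesion molecule ICAM1 rose from 18.4 ± 1.03 to 373.3 ± 15.4 CPM, a log2 fold change of 4.34 ± 0.05 (SE, adjusted p = 9.49e-61). The chemokine genes CXCL10 and CXCL11, whose products attract activated T cells, rose by 5.64 ± 0.07 and 5.13 ± 0.12 on the log2 scale. Over all tested genes 2275 were higher and 2017 lower, of which 595 were at least 2-fold higher and 73 at least 2-fold lower. With library totals in place of TMM scaling the split was 1983 higher and 2690 lower, so that the share of higher calls went from 53% to 42.4%.

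Of 43 NF-kB targets tested, 42 rose, 0 fell and 1 did not pass, with the same counts adjusted over the list alone (median log2 change 2.25, camera adjusted p = 9.29e-09 with an estimated correlation). TNFAIP3 and NFKBIA, which encode inhibitors of the pathway itself, rose by 4.30 ± 0.06 and 2.37 ± 0.04. TRAF1 and BIRC3, which encode parts of TNF receptor signalling complexes, rose by 4.96 ± 0.09 and 4.46 ± 0.06, and NFKB2, a subunit of the transcription factor, rose by 3.11 ± 0.04. For VCAM1, an adhesion molecule that was almost silent before stimulation, 2 counts in the untreated libraries stood against 700 with TNF-α, a ratio of 371 with a 95% exact counting interval of 102 to 3070. Such intervals cover counting error only. Of 39 interferon-stimulated genes, 37 rose and 2 did not pass, again with the same counts adjusted over the list alone (median 0.80). Their camera adjusted p was 1.08e-53, or 1.99e-06 with an estimated correlation, the measure given for NF-kB targets. GBP5, a guanylate-binding protein, rose by 3.01 and the antiviral enzyme OAS3 by 0.88.

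JAK-STAT pathway genes and STAT3 targets also moved upward as groups. Of 29 JAK-STAT and receptor genes, 16 rose, 5 fell and 8 did not pass, or 17 and 6 adjusted over the list alone (camera adjusted p = 4.74e-07). STAT5A rose by 0.74 ± 0.04, IL6ST, the shared receptor chain of the IL-6 family, by 1.03 and CSF2RB, the shared chain of the IL-3 and GM-CSF receptors, by 0.94. Of 21 STAT3 targets, 11 rose, 3 fell and 7 did not pass, or 14 and 4 adjusted over the list alone (camera adjusted p = 8.73e-10). The transcription factor gene JUNB rose by 1.75 and the survival kinase gene PIM1 by 0.98 ± 0.07, while MYC fell by 0.51 and STAT3 itself by 0.12. STAT5 targets went both ways, with 7 higher, 9 lower and 9 not passing, or 8 and 10 adjusted over the list alone (camera adjusted p = 0.883). Their median was -0.03 although their mean was 0.08. Among them PIM2 rose by 1.17 ± 0.07, and CISH, a negative regulator of cytokine signalling that STAT5 induces, fell by 0.40 (SE 0.09, adjusted p = 0.00042). Of 43 MYC targets and ribosome biogenesis genes, 1 rose, 21 fell and 21 did not pass, or 1 and 22 adjusted over the list alone, among them RRS1 at -0.38 and WDR43 at -0.29. Their camera call (adjusted p = 0.00056) was lost at adjusted p = 0.109 with an estimated correlation, and with library totals 0 rose and 28 fell.

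Of 32 genes of ERK feedback and the immediate-early response, 13 rose and 8 fell, or 16 and 8 adjusted over the list alone (camera adjusted p = 8.22e-06), with the phosphatase gene DUSP4 up by 1.69. Of 24 BCL2 family and cell death regulators, 11 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.83e-12). Among them the survival gene BCL2A1 rose by 2.25, the pro-apoptotic gene BMF by 2.43 and the death receptor FAS by 1.49. The genes that fell most changed less: the cadherin FAT4 was at -1.55 ± 0.14, the lipid enzyme GPAT3 at -1.49 and the iron exporter SLC40A1 at -1.30.

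MCL induced the oxidative stress response and lowered many of the genes that TNF-α had raised. HMOX1, which encodes the haem-degrading enzyme heme oxygenase and is a classical target of the transcription factor NRF2, went from 0.482 ± 0.165 CPM with TNF-α to 63.7 ± 4.71 CPM with MCL, a log2 change of 7.03 ± 0.15 (adjusted p = 8.94e-24). Transcripts of ICAM1 fell to 172.8 ± 2.39 CPM (log2 change -1.11 ± 0.04, adjusted p = 3.22e-34), and VCAM1 fell by 2.73. In all, 1757 genes were higher and 2442 lower than with TNF-α alone, 124 and 351 of them at least 2-fold. With library totals the split was 2381 higher and 2054 lower, 53.7% higher in place of 41.8%. The mitochondrial share of counts was lower than with TNF-α, as given above.

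Of 31 NRF2 targets, 27 rose, 1 fell and 3 did not pass, the same as adjusted over the list alone (median 1.02). Camera gave them an adjusted p of 3.5e-166, or 1.16e-07 with an estimated correlation. OSGIN1 rose by 5.03 ± 0.08, the quinone reductase NQO1 by 3.53 ± 0.15, SRXN1 by 3.36, GCLM, a subunit of the enzyme that limits glutathione synthesis, by 3.10 ± 0.07 and the cystine transporter SLC7A11 by 3.07 ± 0.06. The member that fell was the transporter gene ABCC1 at -0.19, named after its value was seen. Chaperones rose with them: of 27 heat shock response genes 19 were higher and 1 lower, or 20 and 1 adjusted over the list alone. Their camera adjusted p was 1.12e-30, or 0.000834 with an estimated correlation. HSPA1B rose by 1.99 ± 0.05, HSPA1A by 2.09 ± 0.38 and the co-chaperone DNAJB1 by 1.06 ± 0.04. HSPA1A and HSPA1B are near-identical copies on chromosome 6, so reads may have been divided between them. Of 28 genes of the ATF4 and integrated stress response, 22 rose and 1 fell, or 22 and 2 adjusted over the list alone. Camera gave these genes an adjusted p of 1.64e-28, or 0.000504 with an estimated correlation. Among them CHAC1, which degrades glutathione, rose by 1.74 ± 0.07. SLC7A11, given above with the NRF2 targets, belongs to this list as well and rose by more. The member that fell was the cytokine gene GDF15 at -1.57 ± 0.29, named after its value was seen. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 14 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.21e-06), among them HERPUD1 at 0.66 and the chaperone HSPA5 at 0.38.

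Of the 43 NF-kB targets, 33 fell, 5 rose and 5 did not pass, the same as adjusted over the list alone (median -0.41, camera adjusted p = 9.21e-26). TNFAIP2 fell by 1.27, the cytokine genes LTB by 1.53, EBI3 by 1.43 and TNF by 0.78, and NFKBIA by 0.33. The neutrophil chemokine CXCL8 went the other way and rose by 1.04 ± 0.05 (adjusted p = 6.33e-22). Its relatives CXCL3 and CXCL2, named after their values were seen, rose as well, CXCL3 from 56.4 to 125.9 CPM (adjusted p = 7.96e-30) and CXCL2 by 0.58 ± 0.06 on the log2 scale. Of the 39 interferon-stimulated genes, 29 fell and 0 rose, or 31 and 0 adjusted over the list alone (median -0.55, camera adjusted p = 4.83e-25). Among them IFIT1, an RNA-binding antiviral protein, fell from 95.2 ± 2.84 to 42.7 ± 1.92 CPM.

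The lists of the STAT pathway also fell with MCL. Their medians were -0.17 for STAT5 targets, -0.15 for STAT3 targets and -0.17 for JAK-STAT and receptor genes. NF-kB targets were at -0.41 and interferon-stimulated genes at -0.55. The difference in size between lists was not tested, and single members fell by more than these medians. STAT5A was at -0.60 ± 0.04 (adjusted p = 3.13e-17) and STAT5B at -0.54 ± 0.04, while STAT3 was at -0.05 (adjusted p = 0.369). Of 25 STAT5 targets, 13 fell, 5 rose and 7 did not pass, the same as adjusted over the list alone (median -0.17, camera adjusted p = 0.000149). The anti-apoptotic gene BCL2L1 fell by 0.67 (SE 0.05, adjusted p = 1.06e-17), the cyclin gene CCND1 by 0.73 and PIM2 by 0.76, whereas PIM1 rose by 0.38 and MYC was at -0.06 (adjusted p = 0.228). The repressor gene NFIL3, named after its value was seen, rose by 0.73. CISH was at -0.27 ± 0.10 with an adjusted p of 0.0315. That call was lost without TNF-α replicate 1 (-0.23, adjusted p = 0.135), TNF-α replicate 3 (-0.23, adjusted p = 0.123), MCL replicate 1 (-0.15, adjusted p = 0.33) or MCL replicate 3 (-0.25, adjusted p = 0.0895), and also with library totals (adjusted p = 0.059), without a filter (adjusted p = 0.0524) and with DESeq2 (adjusted p = 0.109). Of 21 STAT3 targets, 10 fell and 3 rose, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.000757), and of the 29 JAK-STAT and receptor genes 16 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 1.04e-05). The adaptor gene SH2B3 fell by 0.49 and TYK2 by 0.51. Of the 32 ERK feedback and immediate-early genes, 15 fell and 3 rose, or 17 and 3 adjusted over the list alone (camera adjusted p = 0.000431). The largest fall among them was that of IER3 at -2.42 ± 0.21.

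**Figure D2:**
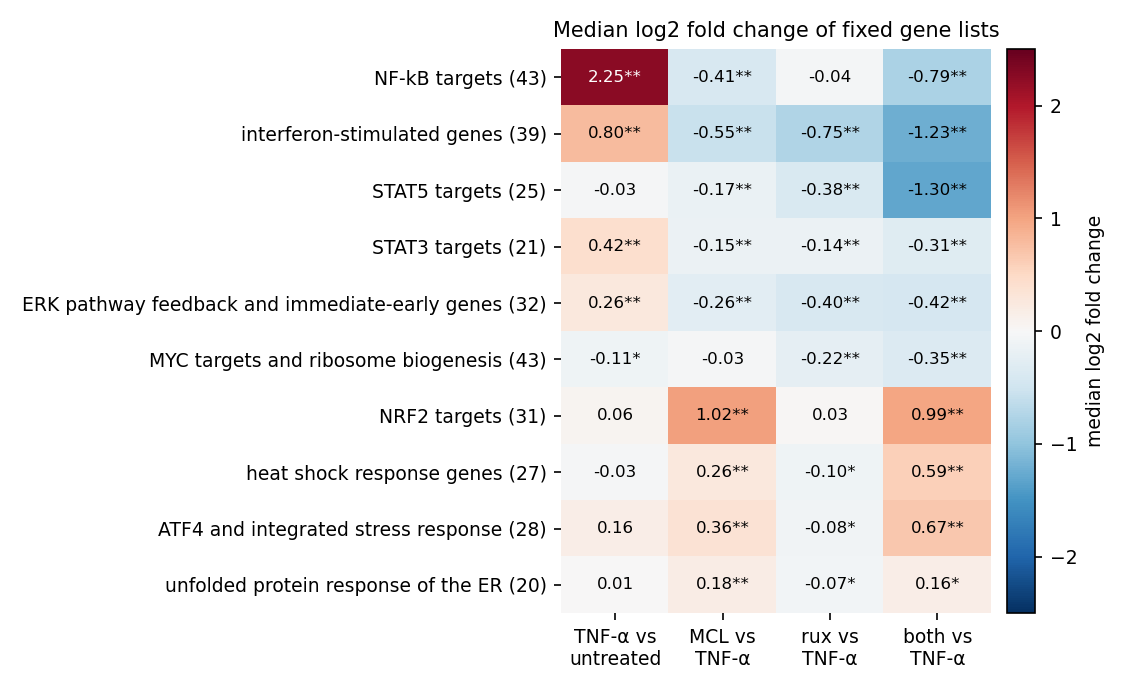
Median log2 fold change of 10 gene lists, with the number of tested members in brackets, in 4 comparisons (columns). Colour and number give the median, 1 asterisk a camera adjusted p under 0.05 and 2 asterisks one that also held with an estimated correlation. NF-kB targets were at 2.25 with TNF-α, -0.41 with MCL, -0.04 with ruxolitinib and -0.79 with both drugs.

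Ruxolitinib lowered interferon-stimulated genes, STAT5 targets, ERK feedback genes and MYC-related genes, while NF-kB targets as a group did not pass. IFIT1 went from 95.2 ± 2.84 CPM with TNF-α to 12.5 ± 1.43 CPM, where untreated cells had 33.7 ± 0.727 CPM (log2 change against TNF-α -2.94 ± 0.07, adjusted p = 6.56e-41). Transcripts of ICAM1 stood at 379.0 ± 5.57 CPM against 373.3 ± 15.4 CPM with TNF-α alone (0.02, adjusted p = 0.776). In all, 832 genes were higher and 1706 lower, 33 and 104 of them at least 2-fold. With library totals the split was 1181 higher and 1418 lower, 45.4% higher in place of 32.8%.

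Of the 39 interferon-stimulated genes, 32 fell, 1 rose and 6 did not pass, or 34 and 1 adjusted over the list alone (median -0.75, camera adjusted p = 8.6e-129). IFIT5 fell by 3.13, OASL by 2.44 and IFI44L by 2.13, and STAT2, a transcription factor of the interferon response, fell by 0.76. IFIT1 and IFIT3 overlap LIPA on the opposite strand. Of the 43 NF-kB targets, 8 rose, 8 fell and 27 did not pass, or 10 and 11 adjusted over the list alone (camera adjusted p = 0.341). The cytokine genes LTA, IL1B, LTB and TNF fell by 1.47, 0.90, 0.88 and 0.55, whereas CD83 rose by 0.44 and NFKBIA by 0.17. TNFAIP3 was at 0.09 (adjusted p = 0.0927), and passed with DESeq2 size factors (adjusted p = 0.0425), library totals (0.0269), DESeq2 (0.0434) or a fit of only these groups (0.0418).

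Of the 25 STAT5 targets, 16 fell, 0 rose and 9 did not pass, or 17 and 0 adjusted over the list alone (median -0.38, camera adjusted p = 7.91e-25). CCND1 fell by 1.21, the repressor gene GFI1B by 0.82, CISH by 0.73 (SE 0.10, adjusted p = 4.75e-08), BCL2L1 by 0.61 and MYC by 0.53. CISH and BCL2L1 overlap tested genes on the opposite strand. Of the 21 STAT3 targets, 8 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 4.59e-06), with PIM1 at -0.39 and STAT3 at -0.09 (adjusted p = 0.0785). Of the 32 ERK feedback and immediate-early genes, 14 fell and 1 rose, or 17 and 1 adjusted over the list alone (median -0.40, camera adjusted p = 1.66e-25). The MAP kinase phosphatases DUSP4 and DUSP6, which are induced by ERK signalling, fell by 1.35 and 1.11, and DUSP5 fell from 105.6 to 49.2 CPM (adjusted p = 2.7e-29). Of the 43 MYC targets and ribosome biogenesis genes, 33 fell and 0 rose, or 36 and 0 adjusted over the list alone (camera adjusted p = 1.49e-18), such as the RNA polymerase I subunit POLR1B at -0.51 and the nucleolar helicase DDX21 at -0.39. NRF2 targets did not pass, with 6 higher, 4 lower and 21 not passing, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.534). Heat shock, ATF4 and unfolded protein response genes were lower on balance, with 12 of 27, 11 of 28 and 8 of 20 that fell, or 12, 12 and 8 adjusted over the list alone (camera adjusted p = 0.0155, 0.00831 and 0.00252). These calls were lost, with adjusted p = 0.368, 0.245 and 0.184 with an estimated correlation. The 29 JAK-STAT and receptor genes went from a call, with 3 higher and 4 lower, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.0474), to adjusted p = 0.184 with an estimated correlation, and with library totals 6 were higher and 3 lower. Among genes that rose, the pro-apoptotic BMF was at 0.87 ± 0.06 and KLHL24 at 0.78.

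Set directly against each other, MCL and ruxolitinib differed in NRF2 targets, in heat shock and ATF4 genes, in NF-kB targets and in interferon-stimulated genes. HMOX1 was higher with MCL by 6.91 on the log2 scale, and VCAM1 and ICAM1 were lower by -3.17 and -1.13. IFIT5 and IFIT1 were higher with MCL by 2.42 and 1.78, as ruxolitinib had lowered them further. In this comparison 2311 genes were higher and 2123 lower with MCL, 152 and 285 of them at least 2-fold.

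Of 31 NRF2 targets, 27 were higher with MCL, or 29 adjusted over the list alone (camera adjusted p = 4.28e-149). Of 27 heat shock response genes 21 were higher and 1 lower, or 23 and 1 adjusted over the list alone and 21 and 0 with library totals (camera adjusted p = 8.76e-39 with TMM), and of 28 ATF4 genes 25 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 1.33e-37). Of 43 NF-kB targets 27 were lower and 7 higher, or 28 and 7 adjusted over the list alone (camera adjusted p = 4.87e-20). Of 39 interferon-stimulated genes 22 were higher and 6 lower, or 24 and 7 adjusted over the list alone (camera adjusted p = 6.48e-13). STAT5 targets were higher with MCL in 11 of 25 and lower in 2, or 12 and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.000693), with CISH at 0.46 ± 0.10 and MYC at 0.47. STAT5A was lower with MCL at -0.58, and BCL2L1 stood at -0.06 between the drugs (adjusted p = 0.428). MYC targets and ribosome biogenesis genes were higher with MCL in 33 of 43 and lower in 0, or 33 and 1 adjusted over the list alone (camera adjusted p = 3.17e-09). The phosphatase genes DUSP4 and DUSP5 were higher by 1.62 and 1.04.

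The changes brought by each drug overlapped. Of 16146 genes, 271 were higher with both single drugs and 767 lower, where independent lists of these lengths would share 90.5 and 258, and 302 moved in opposite directions. The correlation of the log2 changes across genes, which are not independent replicates, was 0.387. Unchanged groups simulated against the same TNF-α libraries gave 0.501 with no effect at all, and their count of genes moved the same way had a mean of 0. With no effect hardly any gene can pass the adjusted threshold, so that count was built in. The covariance was 0.0578 against a simulated 0.0259. There were 3 TNF-α libraries, too few to divide, so part of the excess overlap may come from the shared controls.

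With both drugs, the NF-kB, interferon and STAT5 groups fell further than with either drug, and heat shock and ATF4 genes rose further. ICAM1 stood at 43.0 ± 2.33 CPM (log2 change against TNF-α -3.12 ± 0.04), against 172.8 ± 2.39 with MCL and 379.0 ± 5.57 with ruxolitinib. The transcript of TNF itself fell by 3.95 (SE 0.09), from 54.0 to 3.50 CPM. HMOX1 reached 539.2 ± 26.2 CPM, a log2 change of 10.11 ± 0.11 against TNF-α. Against TNF-α alone 4110 genes were higher and 4730 lower, 632 and 1354 of them at least 2-fold. With library totals the split was 5091 higher and 3900 lower, 56.6% higher in place of 46.5%. The mitochondrial share was the lowest of the 5 groups.

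Of the 43 NF-kB targets, 34 fell and 4 rose against TNF-α, or 34 and 5 adjusted over the list alone (median -0.79, camera adjusted p = 1.46e-31). EBI3 fell by 3.15, TNFAIP2 by 3.07 and BCL2A1 by 2.48. The chemokine genes CXCL3 and CXCL8 rose by 2.41 ± 0.05 and 0.95, as did CXCL2, named after its value was seen, by 0.94. Of the 39 interferon-stimulated genes, 38 fell and 0 rose, or 39 and 0 adjusted over the list alone (median -1.23, camera adjusted p = 1.13e-33), and of the 25 STAT5 targets 20 fell and 3 rose, also adjusted over the list alone (median -1.30, camera adjusted p = 3.27e-14). CISH fell by 1.40 (SE 0.11, adjusted p = 1.07e-17), BCL2L1 by 1.36, CCND2 by 1.32, MYC by 1.30 and CCND1 by 2.94, while PIM1 rose by 0.88 and NFIL3, named after its value was seen, by 1.43. Levels of BCL2L1 were 98.9 ± 4.43 CPM with TNF-α, 62.2 ± 2.35 with MCL, 64.9 ± 2.77 with ruxolitinib and 38.6 ± 1.83 with both. STAT5A fell by 1.46 and STAT5B by 0.93. Of the 21 STAT3 targets, 12 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 9.22e-07), and of the 29 JAK-STAT and receptor genes 15 fell and 5 rose, or 15 and 6 adjusted over the list alone (camera adjusted p = 1.67e-05). With library totals 11 STAT3 targets fell and 7 rose, and 12 JAK-STAT and receptor genes fell and 8 rose. Of the 43 MYC targets and ribosome biogenesis genes, 38 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 1.46e-07), with RRS1 at -1.41. Of the 32 ERK feedback and immediate-early genes 17 fell and 4 rose, or 22 and 4 adjusted over the list alone (camera adjusted p = 0.000197), with JUNB at -1.87.

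Of the 27 heat shock response genes, 24 rose and 3 fell, also adjusted over the list alone (median 0.59, camera adjusted p = 1.13e-36), with HSPA1B at 4.41 ± 0.05, DNAJB4 at 4.28 and DNAJB1 at 2.80 ± 0.04. Of the 28 ATF4 and integrated stress response genes, 22 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 1.16e-25). CHAC1 rose by 3.25, ATF3 by 2.73, DDIT3, which encodes the stress-induced transcription factor CHOP, by 2.30 ± 0.11 and SESN2 by 2.03. GDF15, named after its value was seen, fell by 1.32. Of the 31 NRF2 targets, 25 rose and 2 fell, or 25 and 3 adjusted over the list alone (median 0.99, camera adjusted p = 1.56e-57), and of the 20 unfolded protein response genes 12 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00174). The last call was lost at adjusted p = 0.125 with an estimated correlation. With library totals 1 gene fell in each of the heat shock and unfolded protein response lists.

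**Figure D3:**
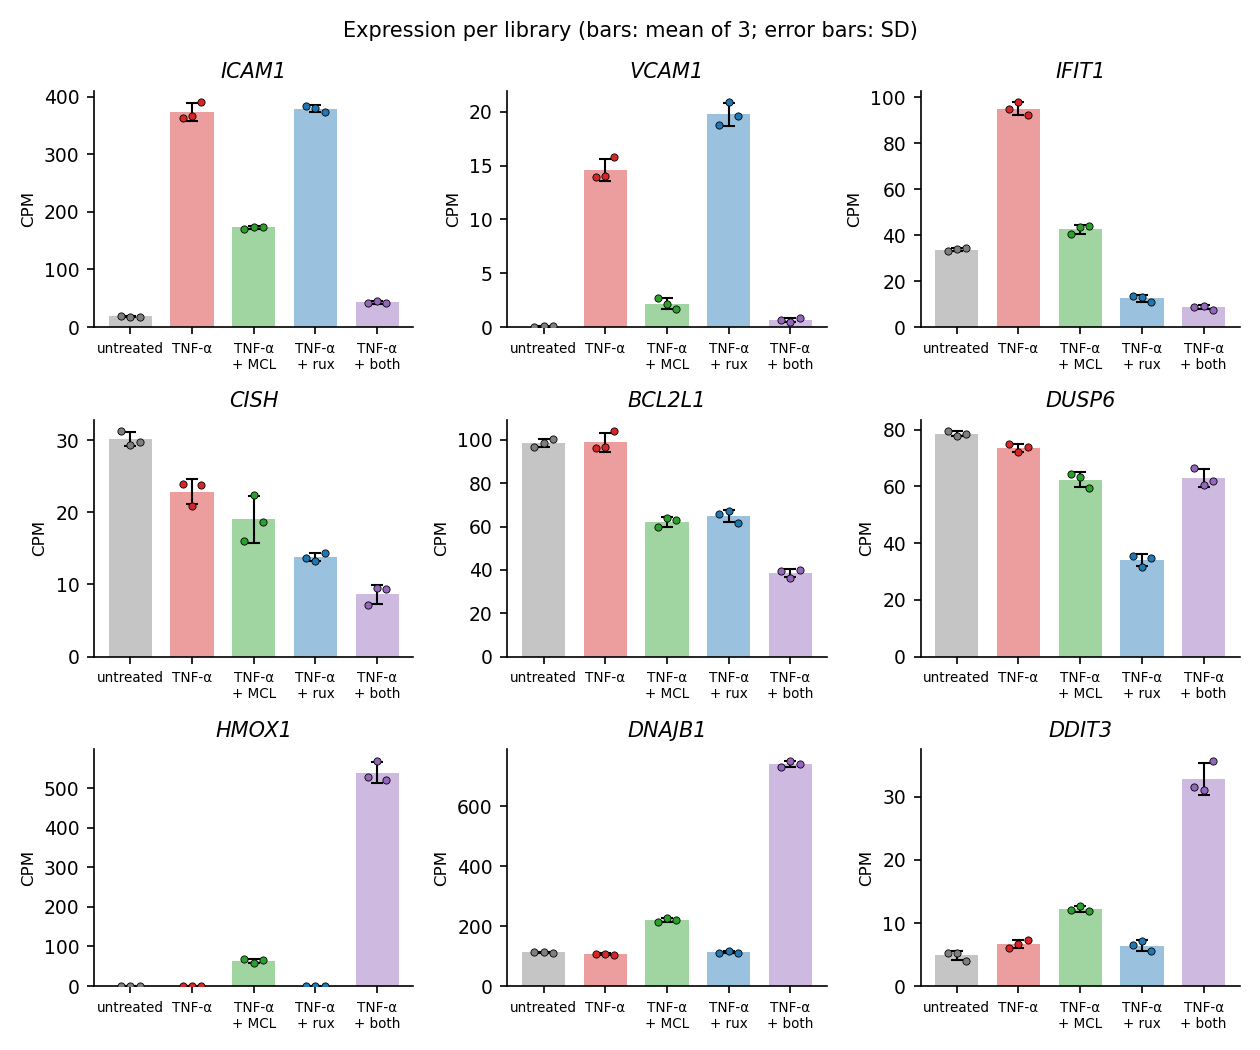
Expression of 9 genes in CPM (y axes, from 0) in the 5 groups (x axes); bars are means of 3 libraries, error bars the SD, and points the libraries. ICAM1 was at 172.8 CPM with MCL, 379.0 with ruxolitinib and 43.0 with both, and HMOX1 at 63.7, 0.529 and 539.2.

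Against ruxolitinib alone, adding MCL gave 4012 higher and 4335 lower genes, and against MCL alone, adding ruxolitinib gave 3170 higher and 3553 lower genes. With library totals most calls were higher instead, with 4719 higher and 3689 lower against ruxolitinib and 3764 higher and 2976 lower against MCL. Compared with ruxolitinib, 32 of 43 NF-kB targets were lower and 5 higher, or 32 and 6 adjusted over the list alone (camera adjusted p = 7.85e-36), with ICAM1 at -3.14 and TNF at -3.40. Interferon-stimulated genes were lower in 28 of 39 and higher in 2, also adjusted over the list alone (camera adjusted p = 0.000192), and STAT5 targets were lower in 17 of 25 and higher in 5, also adjusted over the list alone (camera adjusted p = 2.54e-05), with CISH at -0.67 ± 0.11 and MYC at -0.77. Compared with MCL, 37 of 39 interferon-stimulated genes were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 7.66e-29), with IFIT5 at -3.31. STAT5 targets were lower in 16 of 25 and higher in 2, also adjusted over the list alone (camera adjusted p = 5.06e-19), with MYC at -1.24 and CISH at -1.13. Heat shock response genes were higher in 22 of 27 and lower in 3, also adjusted over the list alone (camera adjusted p = 5.83e-32), with HSPA1B at 2.42, and HMOX1 was higher by 3.08 ± 0.06. The cholesterol exporter ABCA1 and the transcriptional repressor BCL6 were higher than with MCL alone by 2.27 and 2.11.

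The combination was not the sum of the single drugs for 4033 genes, 1962 with a positive and 2071 with a negative non-additive effect, 178 and 301 of them at least 2-fold. With library totals 2168 were positive and 1889 negative. ICAM1, which ruxolitinib alone left at 0.02, had a non-additive effect of -2.03 ± 0.06. The heat shock gene HSPA1B had one of 2.81 ± 0.08 and DNAJB1 one of 1.67 ± 0.05. For BCL2L1 the value was -0.08 (adjusted p = 0.461), so that a departure from the sum was not detected there.

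Of the 43 NF-kB targets, 31 had a negative and 5 a positive non-additive effect, or 32 and 5 adjusted over the list alone (camera adjusted p = 6.7e-35). TRAF1 was at -2.24, EBI3 at -2.04 and TNFAIP2 at -1.76, while the chemokine CXCL3 and the regulator NFKBIZ, named after their values were seen, were at 1.20 ± 0.07 and 0.87 ± 0.09. Of the 27 heat shock response genes, 19 were positive and 1 negative, or 21 and 1 adjusted over the list alone (camera adjusted p = 2.68e-39), and of the 28 ATF4 genes 21 were positive and 1 negative, or 22 and 1 adjusted over the list alone (camera adjusted p = 6.56e-22), with SESN2 at 1.75, ATF3 at 1.59 and CHAC1 at 1.38. Of the 25 STAT5 targets 13 were negative and 5 positive, also adjusted over the list alone (camera adjusted p = 9.89e-05), with MYC at -0.71 ± 0.05. Interferon-stimulated genes did not pass as a group, with 12 positive, 8 negative and 19 not passing, or 15 and 9 adjusted over the list alone (camera adjusted p = 0.259). Among genes that MCL alone lowered, 928 had a negative and 191 a positive non-additive effect, and among those it raised, 598 had a positive and 130 a negative one. Among genes with no call for MCL alone, 1013 had a negative and 1173 a positive one. Sorted by ruxolitinib alone, the genes it raised had 267 negative and 122 positive effects. Those it lowered had 380 and 406, and those without a call 1424 and 1434. The non-additive effect subtracts each single-drug change, so noise alone pushes its sign against that of the drug used for sorting. The excess of negative effects among genes that ruxolitinib raised cannot be told apart from this. The excesses among genes sorted by MCL ran the other way.

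**Figure D4:**
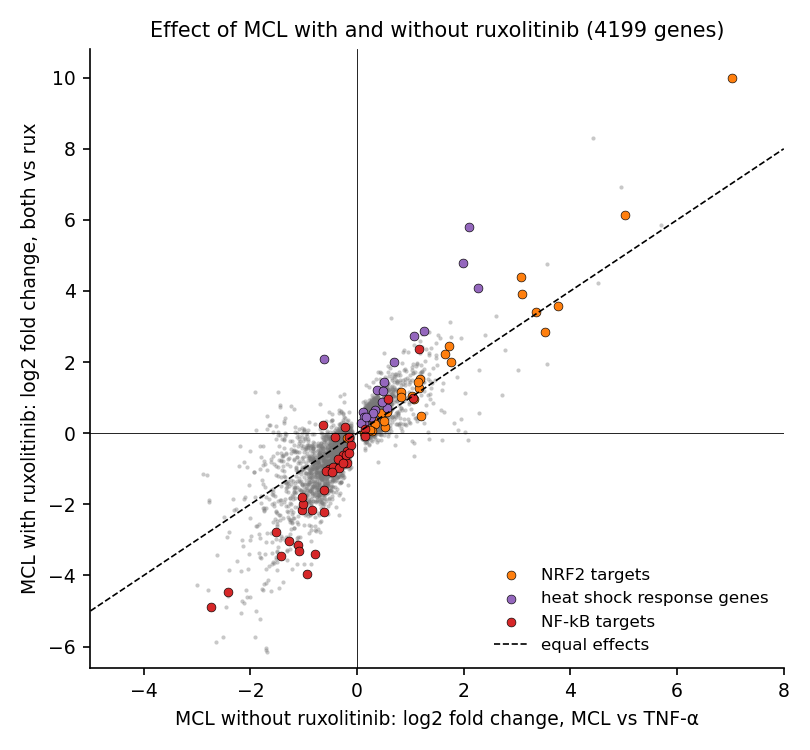
Log2 fold change of MCL without ruxolitinib (x axis, MCL against TNF-α) and with it (y axis, both drugs against ruxolitinib) for the 4199 genes that passed in the first comparison, with members of 3 lists in colour and a dashed line of equal effects. The axes share no library, and 92.5% of these genes had the same sign on both.

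The comparison of the drug effects with the TNF-α response asked how far the genes raised by TNF-α were lowered and those lowered by it were raised. Of the 595 genes that TNF-α raised at least 2-fold, MCL lowered 365 (61.3%), ruxolitinib 98 (16.5%) and the combination 452 (76%). Their median log2 change was 1.57 with TNF-α and then -0.71 with MCL, -0.06 with ruxolitinib and -1.33 with both. Of all 2275 genes raised by TNF-α, MCL lowered 1059 and raised 170, ruxolitinib lowered 398 and raised 238, and the combination lowered 1297 and raised 469. Of the 2017 genes lowered by TNF-α, MCL raised 436 and lowered 387 further, ruxolitinib raised 136 and lowered 592 (29.4%, against 17.5% of the raised genes), and the combination raised 544 and lowered 879 (43.6%). These comparisons share the TNF-α libraries. In simulations with the TNF-α effect and no drug effect, the counts of raised genes then lowered had means of 0.6 for MCL, 0.1 for ruxolitinib and 0 for both. Without a drug effect hardly any gene can pass in the drug comparison, so these low counts were built in. For genes raised at least 2-fold, the simulated median log2 change with MCL was -0.037, against -0.71 observed. Across genes the log2 change with MCL had a correlation of -0.415 and a covariance of -0.103 with that of TNF-α, where unchanged groups gave -0.506 and -0.0259.

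In the hg38 coordinates of the table, ICAM1 lies on chromosome 19 from 10270835 to 10286615 on the plus strand, HMOX1 on chromosome 22 from 35380361 to 35394214 on the plus strand and VCAM1 on chromosome 1 from 100719742 to 100739045 on the plus strand. IFIT1 lies on chromosome 10 from 89392546 to 89406486 on the plus strand and overlaps LIPA on the minus strand. CISH lies on chromosome 3 from 50606490 to 50611831 on the minus strand and overlaps MAPKAPK3, and BCL2L1 on chromosome 20 from 31664452 to 31723989 on the minus strand and overlaps ABALON. The counts cover whole genes, so exons and untranslated regions were not measured apart. Other named genes that overlap a tested gene, and whose counts are uncertain for that reason, include CCND1, DDIT3, DNAJB1, DUSP6, OSGIN1, SLC7A11, JUNB, TNFAIP3, FAS, SH2B3 and GFI1B.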

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

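The splits of the libraries and the tests of scaling and of the slope were chosen only after the result was seen, the test by expression level before. In this part each value is a non-additive effect on the log2 scale, marked because the effect of MCL with ruxolitinib differed from that without it in a direct test of the difference. Such a difference was found for 4033 genes.

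The 5 genes with the highest values were EIF3CL at 4.48, HSPA1A at 3.72, HMOX1 at 2.96, HSPA1B at 2.81 and HSPA6 at 2.69, and the 5 with the lowest were RNF223 at -4.33, WNT10A at -2.70, IL18R1 at -2.61, TNF at -2.61 and TMCC2 at -2.60. Mean levels over all libraries were low for HSPA6 (3.3 CPM), RNF223 (2.7 CPM) and WNT10A (2.1 CPM). HMOX1 had a higher mean, but its levels with TNF-α and with ruxolitinib, given above, were close to the detection floor, and both enter its value. No counting interval was made for these values, so their sizes are less certain. For EIF3CL, a near-identical copy of EIF3C, the value rested on few libraries: it had 61.7 CPM in TNF-α replicate 3 against 6.25 and 6.67 in the other TNF-α libraries. Its adjusted p of 0.0211 became 0.051 without MCL replicate 3 (4.31), 0.0506 without ruxolitinib replicate 2 (4.46) and 0.0514 without combination replicate 1 (4.05), and without TNF-α replicate 3 its value was 2.53. For 11 further genes the effects were -2.24 for TRAF1, -2.03 for ICAM1, -0.84 for STAT5A, -0.71 for MYC, 1.08 for DUSP5, 1.12 for DUSP6, 1.31 for HSPH1, 1.38 for CHAC1, 1.48 for DDIT3, 1.67 for DNAJB1 and 1.75 for SESN2.

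Among the gene lists, the median non-additive effects were -0.49 for NF-kB targets, -0.23 for STAT5 targets, -0.14 for STAT3 targets, 0.37 for heat shock response genes, 0.49 for ATF4 genes and 0.14 for p53 targets. The STAT3 targets had 7 positive and 8 negative members, or 8 and 9 adjusted over the list alone (camera adjusted p = 0.00174), and the p53 targets 9 and 3, or 10 and 3 adjusted over the list alone (0.00128). Calls lost with an estimated correlation were those of ERK feedback genes at 0.18 (adjusted p = 0.126), NRF2 targets at 0.11 (adjusted p = 0.152), the unfolded protein response at 0.06 (adjusted p = 0.126), MYC targets and ribosome biogenesis at -0.14 (adjusted p = 0.126), glycolysis and HIF targets at -0.14 (adjusted p = 0.314), DNA replication and E2F targets at -0.15 (adjusted p = 0.113) and JAK-STAT and receptor genes at -0.05 (adjusted p = 0.126).

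The first pattern weighed was the combination effect unlike the sum of the single-drug effects. Replacing TMM factors by library totals gave 4057 genes in place of 4033. It moved the median non-additive effect only from 0.006 to 0.025, so a large change in the count was hardly possible. A change in total RNA between groups would be missed by both scalings, so this test leaves scaling undecided. Low counts near the detection floor are unlikely to account for the pattern, since 37.1% of the 9382 genes with a mean of at least 10 CPM passed against 8.18% of the 6764 genes below. The hypothesis that ruxolitinib enlarges the response to MCL stays open: over the 4199 genes that passed with MCL, the slope of the MCL effect with ruxolitinib on that without it was 1.29, but with genes chosen anew and 1 library left out it ranged from 1.09 (without MCL replicate 3) to 1.27, and the lowest value lay under the bound set for this explanation. With the same 4199 genes and 1 library left out, every slope lay above that bound, up to 1.31. Of the 4199 genes, 68.2% had a larger effect of the same sign with ruxolitinib. The slope does not cover the non-additive genes with no call for MCL alone, 1013 negative and 1173 positive.

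Over regroupings of the 12 TNF-α treated libraries, 4 of 100, the real one included, gave at least 4033 genes, and the highest other gave 5802. That regrouping put combination and MCL libraries together in both single-drug roles, which points to the structure of the groups. Since the regroupings mix groups that differ, the share does not measure chance. For the 7 comparisons of 2 groups, 10 splits each are too few for a share under 0.05. Each other split also mixes the 2 groups, which puts their difference into the spread, so a low count there was built in. The real one was the highest in 1 of 10 each time, with 4292 genes for TNF-α, 4199 for MCL, 2538 for ruxolitinib, 8840 for the combination, 8347 and 6723 for the combination against ruxolitinib and against MCL, and 4434 for MCL against ruxolitinib, and the highest other gave 0 each time.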

How the results depend on the processing

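The counts of genes higher and lower in each comparison, of genes with a non-additive effect, of genes moved the same way by both single drugs and of TNF-α-raised genes lowered stayed within 1.5 times their values under every alternative. Counts of genes changed at least 2-fold were not recomputed, and counts of list members were recomputed only for the scaling. In 34 of 184 list tests another scaling moved the count of higher or of lower members by over 1.5 times, mostly with library totals, and where such a count is printed its value with library totals stands beside it. In the settings tried no named gene reversed its direction. Of the genes called in a comparison, the share called again in the same direction was 93.1% to 99.3% with DESeq2 size factors, 88.7% to 96.8% with library totals, 79.6% to 87.7% with DESeq2, 84.8% to 93% without a filter and 84% to 94.8% with a mean of at least 50 counts. Leaving out 1 library gave 3445 to 4127 genes with a non-additive effect, 751 to 947 genes moved the same way by both single drugs, and 880 to 968 genes raised by TNF-α and lowered by MCL. Of 868 results for 280 named genes, 861 passed and 45 of these lost their call in at least 1 setting, mostly with 1 library left out. Apart from CISH with MCL and the non-additive effect of EIF3CL these are not described by name. TNFAIP3 with ruxolitinib gained a call in some settings. Of 184 list tests, 29 lost their call with an estimated correlation. With the replicate block 98 list tests passed in place of 99, and the JAK-STAT and receptor genes with ruxolitinib were no longer called (adjusted p = 0.0528). The replicate block gave 4326 genes for TNF-α, 4239 for MCL, 2584 for ruxolitinib, 8890 for the combination and 4112 for the non-additive effect. The replicate numbers paired no libraries: residuals of libraries with the same number had correlations of -0.0483 to 0.0483, and 5 of 15 libraries were closest to ones with their own number. In the simulation 60% of the genes changed 1.5-fold were recovered for TNF-α and 46% for the non-additive effect. Far fewer genes were changed there than passed in the data, so these shares do not give the sensitivity of the real comparisons.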

Other observations

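The test of the combination against ruxolitinib for shared libraries and the splits were chosen only after the result was seen, apart from the split for the combination among TNF-α-raised genes. The tests of expression level and of ruxolitinib against untreated cells were chosen before. Where a single pair of list counts is given in this part, the counts adjusted over the list alone were the same.

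Cell death regulators changed in both directions with the drugs. The pro-apoptotic gene PMAIP1, a p53 and ATF4 target, rose by 1.12 with MCL and by 2.07 with both drugs. BMF, which ruxolitinib alone raised from 43.1 ± 1.94 to 78.9 ± 3.62 CPM, stood at 22.0 ± 1.27 CPM with both, and its non-additive effect was -1.57. Of 24 BCL2 family and cell death regulators, 1 rose and 10 fell with MCL, also adjusted over the list alone (camera adjusted p = 0.0285), a call lost at adjusted p = 0.0742 with an estimated correlation. With ruxolitinib 5 rose and 6 fell, or 5 and 9 adjusted over the list alone (adjusted p = 0.655), and with both drugs 3 rose and 14 fell (adjusted p = 0.0946), or 6 and 11 with library totals. Of 25 p53 targets, 8 rose and 2 fell with TNF-α (adjusted p = 0.0782), 2 and 11 with MCL (0.147), 4 and 3 with ruxolitinib (0.131), and 12 and 8 with both drugs, or 13 and 8 adjusted over the list alone (0.0676). With both drugs against MCL 13 were higher and 6 lower, or 13 and 7 adjusted over the list alone (adjusted p = 2.36e-05), among them SESN1 at 0.74. Of the ERK feedback genes, DUSP6 and DUSP5 were looked at after their values were seen. DUSP6 stood at 34.0 ± 2.18 CPM with ruxolitinib and 62.9 ± 3.11 with both drugs, and DUSP5 at 49.2 and 99.4 CPM, where MCL alone gave 62.4 ± 2.68 for DUSP6 and 101.2 for DUSP5. Another phosphatase gene, DUSP2, was lower with both drugs than with ruxolitinib at -2.27, and the 32 genes of the list did not pass there (11 higher, 8 lower, median 0.13 but mean -0.12, camera adjusted p = 0.916).

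Lists for growth and metabolism moved by small amounts, and several of their counts depended on the scaling. Of 31 genes of G2/M and mitosis, 9 rose and 0 fell with ruxolitinib, or 14 and 1 adjusted over the list alone (adjusted p = 0.000105), a call lost at adjusted p = 0.0955 with an estimated correlation. With library totals 14 rose and 0 fell. With TNF-α 1 rose and 7 fell (adjusted p = 0.186), with MCL 2 and 10, or 3 and 13 adjusted over the list alone (0.163), and with both drugs 12 and 8, or 13 and 8 adjusted over the list alone (0.233), the spindle gene HMMR among the risen at 0.73. With library totals these counts were 0 and 14 with TNF-α, 3 and 6 with MCL, and 18 and 4 with both drugs. Of 37 DNA replication and E2F targets, 0 rose and 8 fell with TNF-α (adjusted p = 0.186), 7 and 6 changed with MCL (0.957), and 7 rose and 22 fell with both drugs (0.174), with UHRF1 at -0.99. With ruxolitinib 6 rose and 2 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.0186), a call lost at adjusted p = 0.245 with an estimated correlation. With library totals 14 fell with TNF-α and 12 rose with ruxolitinib. Of 23 cholesterol biosynthesis genes, 9 rose and 1 fell with MCL, or 10 and 1 adjusted over the list alone (adjusted p = 0.0223, and adjusted p = 0.102 with an estimated correlation), or 12 and 0 with library totals, while TNF-α (adjusted p = 0.437), ruxolitinib (0.448) and both drugs (0.0558) gave no call. SQLE, an enzyme of the pathway, fell by 0.55 with both drugs. Of 27 glycolysis and HIF targets, 1 rose and 9 fell with ruxolitinib, or 1 and 12 adjusted over the list alone (adjusted p = 0.00512, and adjusted p = 0.204 with an estimated correlation), with the glucose transporter SLC2A1 at -0.45 and hexokinase HK2 at -0.48, and TNF-α (0.363), MCL (0.567) and both drugs (0.0536) gave no call.

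With TNF-α no call was given for NRF2 targets (7 higher, 4 lower, adjusted p = 0.437), heat shock response genes (3 and 7, median -0.03 but mean 0.04, adjusted p = 0.437, or 3 and 11 with library totals), ATF4 genes (15 and 6, adjusted p = 0.212) or the unfolded protein response (3 and 3, adjusted p = 0.437). MYC targets and ribosome biogenesis genes gave none with MCL (4 and 6, adjusted p = 0.771). Among lineage markers, of 21 megakaryocyte and platelet markers 4 rose and 15 fell with both drugs (adjusted p = 0.012), with GP1BA at -1.74 and RAB27B at 1.07. With ruxolitinib 1 rose and 6 fell (adjusted p = 0.00825, and adjusted p = 0.0766 with an estimated correlation), and TNF-α (0.257) and MCL (0.256) gave no call. With both drugs the list tests were not passed by 9 erythroid (adjusted p = 0.615), 15 monocyte and granulocyte (0.397), 12 T and NK cell (0.0999), 12 B and plasma cell (0.178) and 9 fibroblast and stromal markers (0.0754). With MCL, T and NK cell markers (1 higher and 6 lower, or 1 and 7 adjusted over the list alone) and fibroblast and stromal markers (0 and 5) were called at adjusted p = 0.0371 and 0.0327, and lost this at adjusted p = 0.123 and 0.0719 with an estimated correlation. COL6A1 was among them at -1.08, and CD4 at -0.61. Among erythroid markers CA2 rose by 1.69 with both drugs, and GATA1, the erythroid transcription factor named after its value was seen, fell by 0.76. The B cell gene IGKC had 3 counts in untreated libraries and 143 with TNF-α, a ratio of 50.5 with a counting interval of 16.9 to 248.

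The second pattern was the lowering of TNF-α-raised genes by MCL and by the combination. The TNF-α libraries shared by both comparisons are unlikely to account for the lowering by the combination. In the combination against ruxolitinib, which uses none of them, 72.8% of the 595 genes were lower, against 4335 of all 16146 tested genes. That measures MCL in the presence of ruxolitinib and does not decide the case of MCL alone. For MCL alone, simulations with the TNF-α effect and no drug effect gave a mean of 0.6 raised genes then lowered, against 1059. Without a drug effect hardly any gene can pass the adjusted threshold, so that low count was built in. The median log2 change with MCL does not rest on that threshold. For genes raised at least 2-fold it was -0.037 in these simulations, against -0.71 observed, so the shared libraries alone gave a far smaller shift. An effect of MCL on genes of that expression level in general is also unlikely to account for all of the lowering. MCL lowered 48 of 595 expression-matched genes without a TNF-α call (8.07%), against 61.3%, at a median of 3.83 CPM in both sets. Over all 16146 tested genes it lowered 2442. The matched genes had all failed the TNF-α test, which favours genes measured with more noise. They were matched on the mean of all libraries, not on the TNF-α level, so part of the gap may be built in. The hypothesis that MCL acts against the NF-kB response itself was not tested here by a measure of the pathway, which protein data from the same cultures could give. Over 100 regroupings each, 1 for MCL, 2 for ruxolitinib and 4 for the combination, the real one included, reached the real counts of 1059, 398 and 1297, and the highest others were 974, 1424 and 3106. The highest for ruxolitinib and for the combination put a whole real group in the TNF-α role, which points to the structure of the groups. Since these regroupings mix groups that differ, the shares do not measure chance.

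The third pattern was the fall of interferon-stimulated genes with ruxolitinib while NF-kB targets did not fall on balance. The TNF-α libraries shared by both comparisons are unlikely to account for it: in ruxolitinib against untreated cells, 13 of 39 interferon-stimulated genes were higher, against 37 with TNF-α, at a median of -0.06 against 0.80. NF-kB targets were higher there in 42 of 43, at a median of 1.95. In the same comparison 14 interferon-stimulated genes were lower than in untreated cells, between the bounds set. For these 14, loss of the TNF-α-induced part alone would not bring the level under that of untreated cells. With 13 others higher and 12 not passing, the list as a whole gives no answer. For it, it stays open whether ruxolitinib removes interferon signalling that was active before TNF-α was added as well. Ruxolitinib with no TNF-α, which the design does not hold, could test this.

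For the overlap of the single drugs, 4 of 100 regroupings, the real one included, had at least 1038 genes moved the same way. The highest other had 2047 and put the 3 MCL libraries in the TNF-α role, which points to the structure of the groups. Here too the share does not measure chance. Between MCL and the combination 1476 genes were higher and 2173 lower in both, where independent lists would share 447.2 and 715.4. Their correlation across genes was 0.771 against a simulated 0.51 and their covariance 0.268 against 0.026. Between ruxolitinib and the combination 474 were higher and 1230 lower in both, against 211.8 and 499.8, with a correlation of 0.382 against a simulated 0.51 and a covariance of 0.1 against 0.0261. Part of either excess may come from the shared TNF-α libraries, as simulated values of 0.51 with no effect show.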
